A study of Mus musculus with 20 samples.

How the data were processed

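RNA was measured in 20 libraries of granulocyte-macrophage progenitors, the marrow cells that give rise to neutrophils and monocytes. Per the labels, the mice were C57Bl6/N and carried a tamoxifen-regulated Cre recombinase (CreER) at the ROSA26 locus, alone or with floxed alleles of Gls, Mpc2 or both, and the cells were taken about 10 weeks after gene deletion. The labels put 5 libraries in each of 4 groups: wild type (WT), Mpc2 knockout (Mpc2 KO), Gls knockout (Gls KO) and the double knockout (DKO). The labels' protocols name a NucleoSpin RNA XS extraction and a SMARTseq V4 cDNA kit. That kit makes cDNA from full-length polyadenylated transcripts and does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. The labels do not say that the libraries of a group come from separate mice, so every p-value measures the spread between libraries.

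The deposited values are the output of Salmon. For each library the authors deposited an estimated count of reads per transcript that is neither whole nor normalized, made with Salmon 1.5.1 per the submitters' processing notes. The same deposited files give TPM, a transcript abundance scaled for length and depth, which sums to the same total in each library, and an effective transcript length. The genome build, the annotation release and the Salmon options are not given in the sources used here. The authors also deposited a table without a header whose columns hold a mean normalized count, a log2 fold change with its standard error, a score equal to their ratio, a p-value and an adjusted p-value. The processing notes name DESeq2 2.11.40.6. Neither the labels nor that table state its comparison. Its file naming points to Mpc2 KO and WT, and Mpc2 holds its most negative log2 value among genes with an adjusted p under 0.05. No column of values per sample was left unused.

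Transcripts were summed to genes through their identifiers without version numbers, using the GENCODE M21 annotation of mouse build GRCm38, which may not be the authors' build. Of 140789 transcripts, 137161 (97.4%) matched, and 99.6% of those had the same length in both sources. Reads on unmatched transcripts made up 0.614% to 1.27% of a library and were left out. The matched transcripts gave 51717 genes. Estimated counts were rounded to whole numbers. Library totals ran from 11077468 to 23461556 estimated reads (median 19188787). Levels are CPM, estimated counts scaled by library size, after scaling by trimmed mean of M values (TMM), and errors are the SD over 5 libraries unless stated.

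The main test was edgeR 4.0.16's quasi-likelihood test with robust dispersions (R 4.3.3), fitted to all 20 libraries with 1 coefficient per group. Genes had to pass filterByExpr with its minimum count of 10 and minimum total of 15, which left 14434. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 with no fold threshold. The 6 comparisons were each knockout against WT, DKO against each single knockout, and the interaction, which is the difference between the effects of Mpc2 deletion with and without Gls. Fitted log2 fold changes used a prior count of 0.125 and are given with their standard errors (SE). All tests were two-sided.

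Gene lists were tested with camera on voom values (limma 3.58.1) with the correlation between genes preset at 0.01. Of 37 lists written, 36 had at least 5 tested genes, and adjusted p-values cover those 36 within a comparison. Beside camera, the same test with the correlation estimated per list was run, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Member genes were also adjusted over the list alone. With an estimated correlation, 0 lists were called in each of the 6 comparisons, and the lowest adjusted p was 0.173. Fry called 1 list, cholesterol synthesis, in DKO against WT and in DKO against Gls KO, and 0 elsewhere.

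The text names genes by a rule: Gls, Gls2, Mpc1 and Mpc2 in every comparison, up to 10 called genes with the largest rise and up to 10 with the largest fall among those with a mean of at least 2 on the log2 CPM scale, and up to 4 members with the smallest p from each list described. Predicted gene models, pseudogenes and antigen receptor segments were counted but not named under the rule. For comparisons among knockouts fewer genes are named than the rule allows. A few genes outside the rule are named and marked as chosen after their values were seen. The groups, the tests, the gene lists, the rule and the first set of other settings listed below were fixed before the data were examined.

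Near-identical copies of called genes were searched with blastn 2.17.0 among all annotated transcripts, at 95% identity or more over at least 200 bases. Salmon divides reads between such copies, so levels of genes with a copy are uncertain. No deposited library duplicated another: over the 40 pairs within groups, the lowest chi-square per degree of freedom was 6.22. Comparisons against WT share the WT libraries, so their correlation was set beside 20 simulations of unchanged groups and beside 10 splits of the WT libraries into 2 and 3. Group labels were also reassigned in 60 splits per comparison, the real one included.

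The test was checked on counts simulated from the real means and library sizes with 200 of 14434 genes changed. For Mpc2 KO against WT, edgeR called 66 of 100 genes changed by 1 on the log2 scale, 75 of 100 changed by 2, and 2 of 14209 unchanged genes. For Gls KO against WT it called 63, 79 and 8, and for DKO against WT 58, 80 and 5. Each gene was drawn on its own, so this check lacks the variation that genes share within libraries. Its shares of called genes, changed or unchanged, may therefore not hold for the real libraries. The results were recomputed with DESeq2 1.42.0, RLE size factors, no low-count filter, an offset for effective transcript length, a fit of only the groups compared, the replicate number as a block, voom with sample weights, a Y-linked covariate, and leaving out each library in turn. After the data were seen, 5 more were added: the 4 libraries with the fewest transcripts left out, the 2 WT libraries without Xist left out, near-identical copies summed, the level of S100a8 as a covariate, and the slope of expression on transcript length as a covariate. 3 further settings were run, seen and removed because they chose libraries by a measured level: the 6 libraries with most S100a8 left out, and DKO replicates 2 and 3 left out for their Mpc2, with and without the slope as a covariate. That slope is the fit of each gene's deviation in a library on log2 transcript length. Counts of reads carry no molecular identifiers, so the depth given covers counting error only.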

Results

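Granulocyte-macrophage progenitors of 4 genotypes were profiled by RNA sequencing, with 5 libraries each of WT, Mpc2 KO, Gls KO and DKO cells. Mpc2 encodes a subunit of the mitochondrial pyruvate carrier, which brings pyruvate into mitochondria. Gls encodes glutaminase, which turns glutamine into glutamate. The design asks what losing either route of mitochondrial fuel entry, or both, does to the progenitors' transcripts. Totals ran from 11077468 estimated reads in Mpc2 KO replicate 4 to 23461556 in Mpc2 KO replicate 2. The 4 libraries with the fewest transcripts detected were Mpc2 KO replicate 4 (34287) and DKO replicates 4, 1 and 5 (41447, 42131 and 44558), against 47178 to 55703 in the other 16. Genes with 10 or more reads did not share this shortfall. They numbered 13900 in Mpc2 KO replicate 4 and 14452, 14121 and 14195 in DKO replicates 4, 1 and 5. The other 16 libraries had 12883 to 14093. Those 4 libraries also had the highest slopes of expression on transcript length, 0.12 to 0.39 on the log2 scale per doubling of length, against -0.35 to 0.09 in the others. The first principal component held 57.2% of the variance and placed the same 4 libraries apart from the rest, at 16 to 56 against -30.1 to 9.35.

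**Figure D1:**
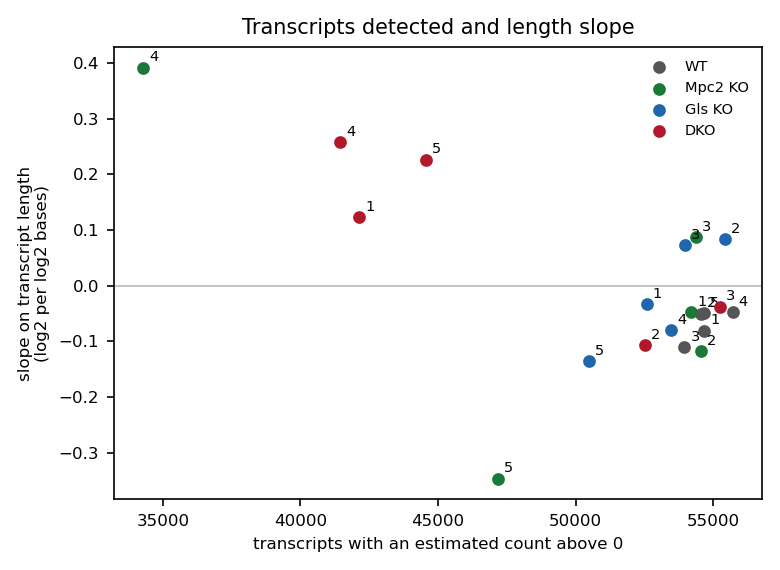
Transcripts with an estimated count above 0 (x axis) against the slope of expression on transcript length (y axis, log2 per log2 bases), 1 point per library, coloured by group and numbered by replicate. DKO replicates 1, 4 and 5 and Mpc2 KO replicate 4 lie at 34287 to 44558 transcripts with slopes of 0.12 to 0.39.

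The targeted genes were examined first. Gls (chromosome 1, 52163448 to 52233232 in GRCm38) was at 174 ± 10.6 CPM in WT and 176 ± 26.2 in Mpc2 KO (SD, n = 5 each). It fell to 13 ± 9.96 CPM in Gls KO (log2 fold change -3.74, SE 0.56, adjusted p = 0.00074) and to 13.9 ± 11 in DKO (-3.65, SE 0.55, adjusted p = 0.00133), with 0.973% to 17.4% of the WT mean left in the 10 libraries. Mpc2 (chromosome 1, 165460637 to 165481214) was at 39.4 ± 3.81 CPM in WT and 37.8 ± 5.49 in Gls KO. It fell to 7.45 ± 3.87 CPM in Mpc2 KO (-2.39, SE 0.37, adjusted p = 0.00874). The libraries labelled DKO shared that loss only in part: against 4.01% to 31.6% in Mpc2 KO, Mpc2 stood at 30.5%, 79.8%, 64.6%, 39.6% and 19% of the WT mean in replicates 1 to 5. The fitted change against WT was -1.10 (SE 0.35, adjusted p = 0.283), which did not pass the test. Every direction given below for DKO therefore refers to libraries as labelled, 2 of which kept over 60% of Mpc2. Counts were summed over whole genes and the labels do not name the floxed exons, so reads outside the deleted part would remain.

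**Figure D2:**
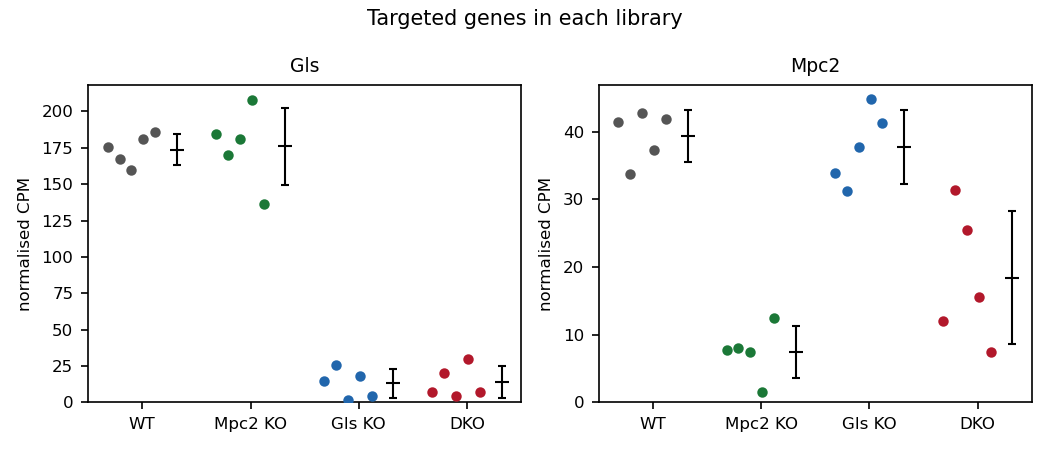
Normalised CPM (y axis) of Gls and Mpc2 in each library, by group (x axis), with the mean and SD as a bar and whiskers beside the 5 points in replicate order. Gls was at 1.69 to 30.2 CPM in the 10 Gls KO and DKO libraries, and Mpc2 reached 31.4 CPM in DKO replicate 2 against 1.58 to 12.4 in Mpc2 KO.

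Neither partner gene passed the test in any of the 6 comparisons. Mpc1, the other carrier subunit, was at 72.1 ± 7.14 CPM in WT and 52.1 ± 17.1 in DKO (-0.47, SE 0.20, adjusted p = 0.399), and Gls2, the second glutaminase gene, averaged under 1 CPM in each group. The libraries also differed in sex-linked RNA. Xist, the RNA of the inactive X chromosome, was at 0.264 and 0 CPM in WT replicates 3 and 4 and at 586 CPM or more in the other 18 libraries, and the mean of 4 Y-linked genes was 49.1 and 53.7 CPM in those WT libraries against 0.466 to 14.8 elsewhere.

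Few transcripts were called with Mpc2 deletion alone. Against WT, 8 of 14434 genes were called, 3 higher and 5 lower, and 433 had an unadjusted p under 0.05. With no change, chance would give such a p to a share of about 0.05 of the tested genes, and 433 is less. Spread within Mpc2 KO was wide: replicates 4 and 5 had voom sample weights of 0.087 and 0.37, against 0.725 or more in Gls KO. DKO weights were low as well, from 0.251 to 0.990, with 52 genes called there against WT. The main fit uses no such weights and shares its estimate of the spread over all groups. These weights therefore do not tell why fewer genes were called here, and a low count does not show that little changed. Bcat1, which encodes the cytosolic aminotransferase of branched-chain amino acids, rose from 15.6 ± 2.35 to 30.6 ± 4.87 CPM (log2 fold change 0.97, SE 0.15, adjusted p = 0.00874) and was higher in each Mpc2 KO library than in any WT library. Alg8, a glucosyltransferase of N-glycan assembly, rose by 0.70 (SE 0.12, adjusted p = 0.0309). Besides Mpc2 itself, the falls were in Ablim1, an actin-binding protein (-1.29, SE 0.21, adjusted p = 0.0153), Hddc3 (-1.14, SE 0.21, adjusted p = 0.0366) and Wdfy1 (-0.60, SE 0.09, adjusted p = 0.00874). Lrmda was the remaining lower gene and Gm6472 the remaining higher one, both named outside the rule after their values were seen. Wdfy1 was lost with the transcript length offset. Without the 2 WT libraries that lack Xist 3 genes were called, without Mpc2 KO replicate 2 there were 2, and the Mpc2 fall itself then had an adjusted p of 0.05 or more in both. Of 20 fits with 1 library left out, Alg8 stayed called in 12, Ablim1 in 15 and Hddc3 in 5.

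In the gene lists, 12 of 36 were called between Mpc2 KO and WT with the preset correlation, and 0 with an estimated one. Immediate early genes were higher, 18 of 18 fitted higher with a median log2 change of 0.82 (adjusted p = 5.47e-05, and adjusted p = 0.811 with an estimated correlation). The 13 genes of the mitochondrial genome were higher, 11 of 13 fitted higher (adjusted p = 0.000642, and adjusted p = 0.811 with an estimated correlation). That call rests on Mpc2 KO replicate 5, with 4.07% of its counts from these genes against 2.32% to 2.68% in the other 4 and 2.24% to 2.51% in WT, and ended without it (adjusted p = 0.969). Genes of NF-kB and inflammatory signalling were higher (adjusted p = 0.00345, and adjusted p = 0.811 with an estimated correlation); Tnf (1.29, SE 0.40), Cxcl2 (2.00, SE 0.62) and Nfkbia (0.73, SE 0.25) passed when adjusted over the list alone. Fatty acid synthesis was lower, 12 of 14 fitted lower (adjusted p = 0.000642, and adjusted p = 0.53 with an estimated correlation), with Fads2 at -0.67 (SE 0.25) and Scd2 at -0.26 (SE 0.11). The interferon response was lower, 21 of 26 (adjusted p = 0.00394, and adjusted p = 0.53 with an estimated correlation). Nuclear oxidative phosphorylation genes (adjusted p = 0.000784), the TCA cycle (0.00277), ribosomal proteins (0.000642), nucleotide synthesis (0.00394), cholesterol synthesis (0.0142) and primary granule genes (0.0455) were also lower, and the ER stress response was higher (0.0433), each with an adjusted p of 0.811 with an estimated correlation. No member of these lists passed over all genes tested, and 3 passed when adjusted over the list alone. Some of these lists followed the library differences above. The mean over oxidative phosphorylation genes lay at -1.29 on the log2 scale from WT in Mpc2 KO replicate 4 and at 0.51 in replicate 5, and that over immediate early genes at 1.80 and 0.82 in replicates 4 and 3 and at -0.10 to 0.23 in the others. With the 4 libraries that had the fewest transcripts left out, oxidative phosphorylation and ribosomal proteins (adjusted p = 0.0807 each) and primary granule genes (0.854) turned higher. Calls ended for the TCA cycle, nucleotide synthesis, NF-kB and immediate early genes, and stayed for the other 5. Of those 5 only the interferon response kept its call with each single library left out. Cholesterol synthesis lost it without Mpc2 KO replicate 1 or 3 or WT replicate 1 (highest adjusted p 0.208), fatty acid synthesis without Mpc2 KO replicate 5 (0.077), and ER stress without Mpc2 KO replicate 1, 2 or 5 or WT replicate 4 (highest 0.884).

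The authors' deposited table, read as Mpc2 KO against WT, held 18 genes with an adjusted p under 0.05, 11 higher and 7 lower, of which 6 also changed by at least 1 on the log2 scale. In the authors' deposited table Mpc2 was at -1.92, Bcat1 at 0.94, Ablim1 at -1.02, Hddc3 at -0.87 and Alg8 at 0.75. Of its 18 genes, 15 were tested in the edgeR fit, all 15 with the same sign, and 6 were called in both, while 2 genes were called only in the fit.

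More genes were called with Gls deletion alone. Against WT, 106 were called, 63 higher and 43 lower, and 851 had an unadjusted p under 0.05. Cd14, the co-receptor for bacterial lipopolysaccharide on monocytes and macrophages, rose from 7.32 ± 1.66 to 26.7 ± 5.05 CPM (log2 fold change 1.86, SE 0.22, adjusted p = 3.81e-05). Fam129c rose from 6.35 ± 0.773 to 17.3 ± 3.70 CPM (1.44, SE 0.22, adjusted p = 0.00076). Fhl2, a LIM-domain protein, rose from 0.936 ± 0.447 to 24.3 ± 2.81 CPM (4.68, SE 0.41, adjusted p = 3.74e-07), and Slc40a1, the iron exporter ferroportin, from 8.54 ± 1.70 to 39.2 ± 12.6 CPM (2.20, SE 0.32, adjusted p = 0.000461). Fhl2 and Slc40a1 lie within 20 Mb of Gls on chromosome 1. Ncmap rose from 0.0301 to 14.7 CPM (8.60, SE 1.57, adjusted p = 0.0119; in 18 of 20 fits with 1 library left out) and St6galnac2, which overlaps a second gene of the same symbol and is uncertain, by 4.64 (SE 1.01, adjusted p = 0.0318; in 11 of 20). Nrg1 (3.40, SE 0.56, adjusted p = 0.00205), Prag1 (1.49, SE 0.20, adjusted p = 0.000208) and Depdc7 (1.32, SE 0.25, adjusted p = 0.00927) rose as well.

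Among the genes that fell, Bcat1 went the other way than in Mpc2 KO, to 2.26 ± 0.408 CPM (-2.78, SE 0.16, adjusted p = 5.49e-10). Kcnip3, a calcium-binding protein, fell from 43.6 ± 2.48 to 2.54 ± 1.17 CPM (-4.11, SE 0.24, adjusted p = 5.49e-10). Hddc3 fell from 14.6 ± 1.52 to 6.02 ± 0.792 CPM (-1.28, SE 0.21, adjusted p = 0.00164). Caskin2 (-2.24, SE 0.29), Jmjd7 (-3.52, SE 0.47), Pbx4 (-2.18, SE 0.42) and Baiap3 (-1.21, SE 0.21) were also lower, with adjusted p of 0.000105, 0.000186, 0.0115 and 0.00369. Several large changes came with an opposite change in a near-identical copy. Kpna2 fell from 181 ± 20.5 to 18.0 ± 7.66 CPM while Gm10184, 99.9% identical over 1968 bases, went from 0.445 to 224 CPM, and Eif3j1 fell from 102 ± 6.43 to 21.4 ± 4.21 CPM while its copy Eif3j2 went from 56.1 to 128 CPM. Hmga1b was at 188 ± 27.1 CPM in Gls KO and 0.273 ± 0.401 in WT while its copy Hmga1 went from 590 to 389 CPM. Transcripts of Hddc3 also share stretches of over 95% identity with other genes. When counts of such copies were summed, 61 genes were called, 34 of them higher. Levels of these genes are therefore uncertain.

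Leaving out 1 library moved the count of 106 to 180 without Mpc2 KO replicate 4 and to 69, 67 and 65 without WT replicates 2, 3 and 4. The folds of Cd14, Fam129c, Fhl2, Prag1, Bcat1, Kcnip3 and Hddc3 stayed called in each of the alternatives that gave them a value, while that of Slc40a1 ended with the transcript length offset (adjusted p = 0.103). With copies summed Hddc3 had no value of its own, and its family was not called there. That family was at 126 CPM in WT and 115 in Gls KO, of which Hddc3 held 14.6 and 6.02. Ncmap, Nrg1, Depdc7, Pbx4, Baiap3 and Bub1b, named below, were lost without the 2 WT libraries that lack Xist.

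**Figure D3:**
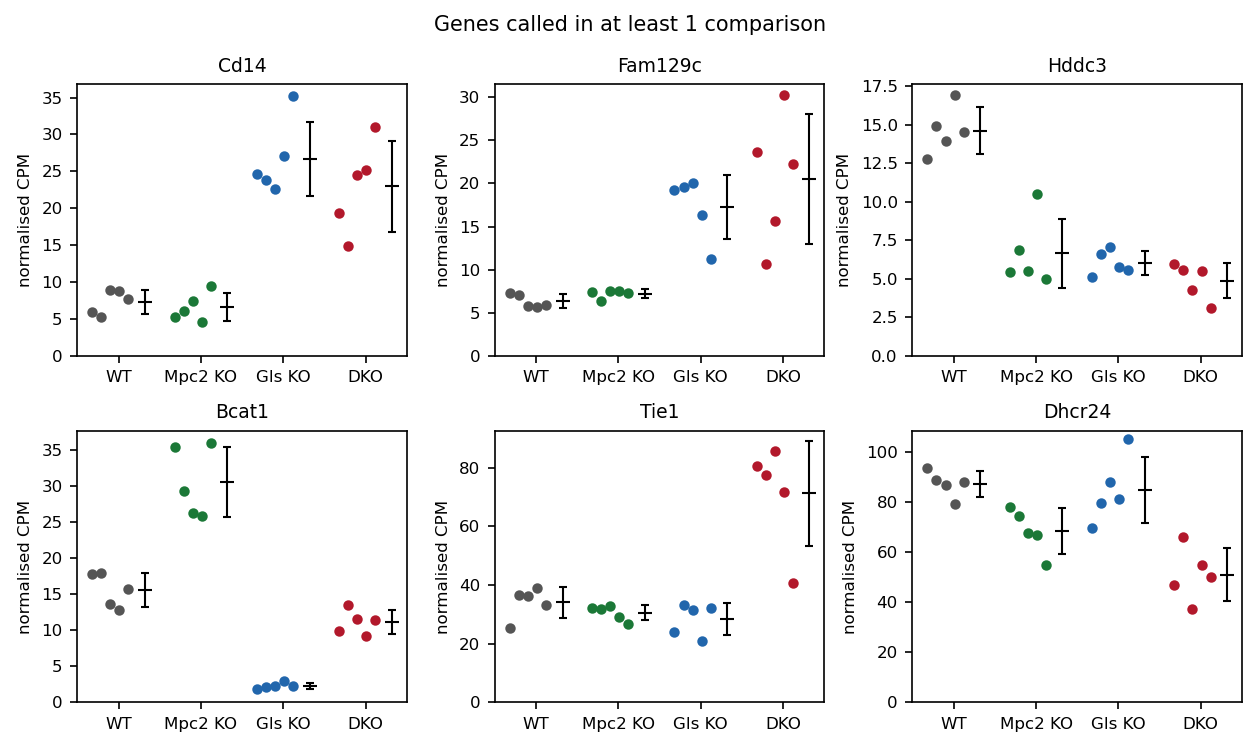
Normalised CPM (y axis, from 0) of 6 genes called in at least 1 comparison, 1 point per library in replicate order by group (x axis), with the mean and SD beside them. Cd14 lay at 14.9 to 35.2 CPM in all 10 Gls KO and DKO libraries and at 4.66 to 9.53 in the other 10, and Bcat1 lay at 25.9 to 36.0 CPM in Mpc2 KO and at 1.79 to 2.91 in Gls KO.

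Proliferation and myeloid lists were higher in Gls KO than in WT with the preset correlation. Of 60 splits of these libraries, the real one included, 54 called 5 or more lists, as many as the real one, so chance cannot be excluded for this count. All 22 genes of the G2 and M phases of the cell cycle were fitted higher, with a median of 0.25 on the log2 scale (adjusted p = 2.22e-10, and adjusted p = 0.545 with an estimated correlation). Bub1b, a spindle checkpoint kinase, was called (0.60, SE 0.12, adjusted p = 0.011), and adjusted over the list alone Bub1b and Top2a (0.29, SE 0.09) passed. Monocyte and dendritic cell genes were higher, 17 of 24 fitted higher with a median of 0.50 (adjusted p = 2.51e-07, and adjusted p = 0.718 with an estimated correlation). Csf1r, the receptor for the monocyte growth factor M-CSF, was called (0.67, SE 0.15, adjusted p = 0.0342; in 11 of 20 fits with 1 library left out), and 8 members passed when adjusted over the list alone, among them Irf8 (0.73, SE 0.19), Klf4 (1.80, SE 0.46) and Ccr2 (0.75, SE 0.18). Gls KO replicate 2 did not share these rises: its list means lay at -0.02 for G2 and M and -0.10 for monocyte genes, against 0.16 to 0.42 and 0.48 to 0.77 in the other 4. Regulators of myeloid progenitors were higher, 15 of 22 (adjusted p = 0.000399, and adjusted p = 0.545 with an estimated correlation), with 4 past the threshold when adjusted over the list alone, of which Csf1r, Irf8 and Klf4 are also in the monocyte list. ER stress genes were higher, 17 of 19 with a median of 0.14 (adjusted p = 0.0424, and adjusted p = 0.898 with an estimated correlation).

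Genes of late neutrophil maturation, 18 of 19 fitted higher, were up by a median of 2.84 (adjusted p = 7.21e-08, and adjusted p = 0.753 with an estimated correlation), and 0 members passed over all genes or when adjusted over the list alone. Retnlg was at 3.61 (SE 1.18), Mmp9 at 3.95 (SE 1.41) and Lcn2 at 1.56 (SE 0.59). The list varied widely between libraries of a group. S100a8, an abundant transcript of mature neutrophils, was at 315 ± 238 CPM in Gls KO (8.37 to 564), 26.6 ± 9.22 in WT, 159 ± 321 in DKO and 72.6 ± 135 in Mpc2 KO, with 734 CPM in DKO replicate 3 and 314 in Mpc2 KO replicate 5. With the level of S100a8 as a covariate none of the 4 lists above stayed called (adjusted p = 0.0724 for G2 and M, 0.0725 for monocyte, 0.0841 for regulators and 0.76 for ER stress genes). S100a8 is itself in the late neutrophil list, which this setting cannot test, and its level differs between the groups, so the covariate also takes up part of a group difference.

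**Figure D4:**
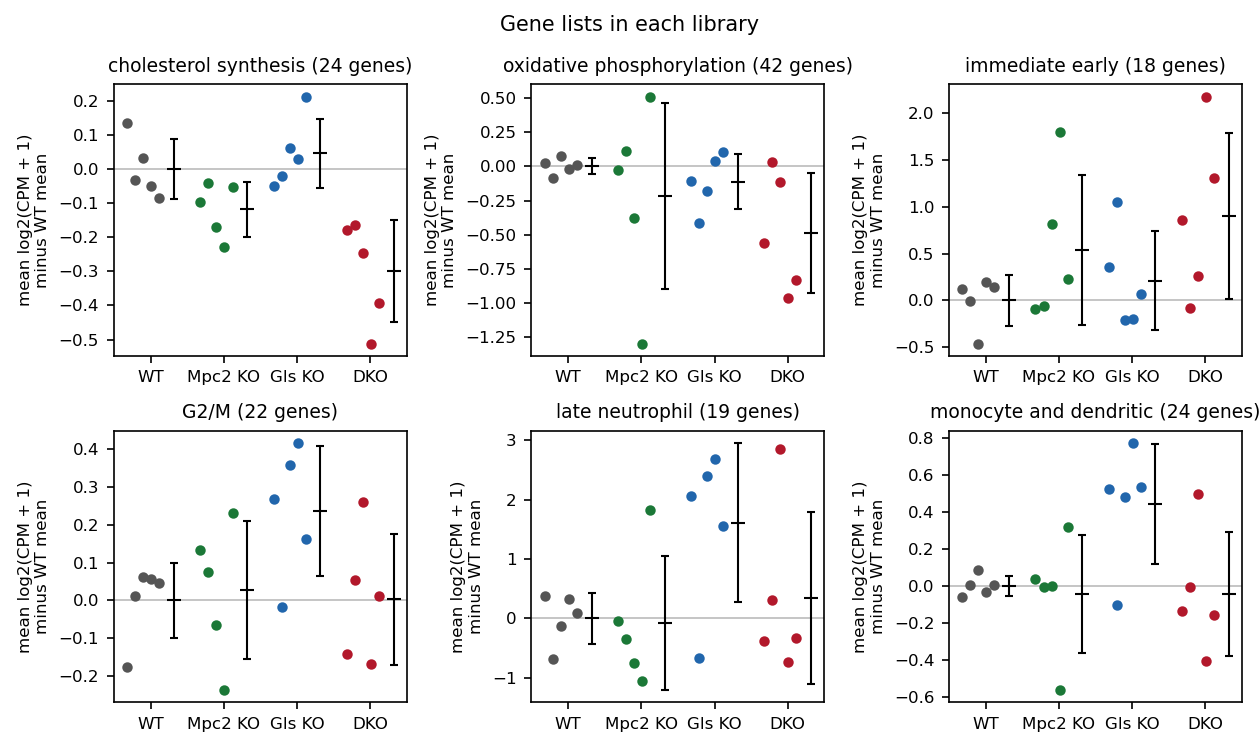
Mean over the genes of 6 lists of log2(CPM + 1) minus the WT mean (y axis), 1 point per library in replicate order by group (x axis), with the mean and SD beside them. Cholesterol synthesis lay below the WT mean in all 5 DKO libraries, while late neutrophil genes ran from -0.67 to 2.68 within Gls KO.

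In the libraries labelled DKO, 52 genes were called against WT, 33 higher and 19 lower, and 1753 had an unadjusted p under 0.05. Several changes were those of Gls KO: Cd14 was at 23 ± 6.12 CPM (log2 fold change 1.65, SE 0.22, adjusted p = 0.000245), Fam129c at 20.5 ± 7.53 (1.69, SE 0.22, adjusted p = 0.000194), Fhl2 at 30.5 ± 4.21 (5.00, SE 0.42, adjusted p = 4.05e-07) and Slc40a1 at 28.1 ± 16.8 (1.72, SE 0.31, adjusted p = 0.00891). Hddc3 fell to 4.90 ± 1.16 CPM (-1.58, SE 0.21, adjusted p = 0.000229), so that it was lower in each of the 3 knockout groups. Pxylp1, a phosphatase of glycosaminoglycan synthesis, fell from 101 ± 5.78 to 52.1 ± 14.1 CPM (-0.96, SE 0.14, adjusted p = 0.000934). Other genes moved against WT and against both single knockouts. Tie1, a receptor kinase of endothelial and blood stem cells, rose from 34.1 ± 5.27 to 71.2 ± 17.9 CPM (1.06, SE 0.17, adjusted p = 0.00286). Hebp1, a heme-binding protein, fell from 29.6 ± 2.1 to 3.35 ± 1.46 CPM (-3.14, SE 0.33, adjusted p = 1.59e-05), and Trim12c from 35.8 ± 2.08 to 19.2 ± 2.34 (-0.90, SE 0.10, adjusted p = 2.51e-05).

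Inppl1 (1.33, SE 0.26), Cited4 (1.41, SE 0.30), Depdc7 (1.24, SE 0.25) and Cbfa2t3 (1.05, SE 0.23) rose, with adjusted p of 0.0189, 0.0459, 0.0248 and 0.0491. Cmpk2 (-1.22, SE 0.21, adjusted p = 0.00538) and Als2 (-0.90, SE 0.16, adjusted p = 0.00637) fell. Hmga1b, Kpna2, Eif3j1 and Rps7 were called too, each with a near-identical copy that moved the other way: Rps7 fell by 1.32 (SE 0.22, adjusted p = 0.00433), while its copy Gm6472 was at 551 CPM in DKO and 0.0308 in WT. Als2 lies within 20 Mb of Gls. Without DKO replicate 2 the count was 209 and without Mpc2 KO replicate 4 it was 96. Of 20 fits with 1 library left out, Inppl1 stayed called in 15, Depdc7 in 13, Kpna2 in 9, Cited4 in 6 and Cbfa2t3 in 5. Slc40a1, Als2, Cmpk2, Hmga1b and Rps7 were lost without the 2 WT libraries that lack Xist, and Pxylp1 without the 4 libraries that had the fewest transcripts. With the transcript length offset Slc40a1 (adjusted p = 0.353), Als2 and Pxylp1 (0.0648 each) were lost too. Tie1, Hebp1, Trim12c, Cd14, Fam129c, Fhl2 and Hddc3 stayed called in every alternative that gave them a value. Hddc3 and Trim12c had a value in 32 alternatives, as did Kpna2, Eif3j1 and Rps7, and the rest of this group of genes in 33. With copies summed, a gene with a near-identical copy has no value of its own, and Trim12c may be such a gene.

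Between DKO and WT, 18 lists were called, 3 higher and 15 lower, and 0 with an estimated correlation. Cholesterol synthesis was lower, 22 of 24 fitted lower with a median of -0.26 on the log2 scale (adjusted p = 1.73e-06, adjusted p = 0.432 with an estimated correlation and adjusted p = 0.0153 with fry). Dhcr24, the last enzyme of 1 branch of that pathway, fell from 87.5 ± 5.2 to 51.1 ± 10.5 CPM (-0.78, SE 0.13, adjusted p = 0.00449). Adjusted over the list alone, 3 members passed: Dhcr24, Sqle (-0.64, SE 0.16), which encodes squalene epoxidase, and Ldlr (-0.75, SE 0.22), the LDL receptor. Without the 4 libraries that had the fewest transcripts Dhcr24 was no longer called, at a similar fold of -0.75 with 2 DKO libraries remaining (adjusted p = 0.135). Nuclear oxidative phosphorylation was lower, 42 of 42 fitted lower with a median of -0.43 (adjusted p = 2.54e-11, and adjusted p = 0.506 with an estimated correlation), and 0 members passed. The TCA cycle was lower, 17 of 18 (adjusted p = 2.92e-05, and adjusted p = 0.505 with an estimated correlation), as were ribosomal proteins, 34 of 35 (adjusted p = 1.29e-06, and adjusted p = 0.56 with an estimated correlation), nucleotide synthesis, 20 of 21 (adjusted p = 1.18e-05, and adjusted p = 0.505 with an estimated correlation) and ribosome biogenesis, 21 of 25 (adjusted p = 0.000731, and adjusted p = 0.505 with an estimated correlation).

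Other falls between DKO and WT were called for pyruvate metabolism (adjusted p = 0.00264), glutamine and glutamate (0.00831), serine and one-carbon metabolism (0.00336), fatty acid synthesis (0.0218), fatty acid oxidation (0.0021), glutathione (0.00803), the mitochondrial stress response (0.00615) and the G1 and S phases (0.00198). With an estimated correlation their adjusted p lay between 0.505 and 0.56. The integrated stress response was called lower (adjusted p = 0.00336, and adjusted p = 0.505 with an estimated correlation) with a median of -0.23 but a mean of 0.02. Immediate early genes were higher, 18 of 18 fitted higher with a median of 1.17 (adjusted p = 2.06e-07, and adjusted p = 0.505 with an estimated correlation), and 7 passed when adjusted over the list alone, among them Klf2 (1.73, SE 0.46), Ier2 (0.66, SE 0.21) and Fos (0.81, SE 0.27). NF-kB genes (adjusted p = 0.00177) and myeloid regulators (adjusted p = 0.00908) were higher as well, each with an adjusted p of 0.505 with an estimated correlation; Gfi1, a transcriptional repressor of granulocyte development, was called (0.37, SE 0.08, adjusted p = 0.0407; in 8 of 20 fits with 1 library left out). The means of oxidative phosphorylation genes differed between DKO libraries in step with the length slope: -0.56, -0.96 and -0.83 in replicates 1, 4 and 5 against 0.03 and -0.11 in replicates 2 and 3. Those of immediate early genes were 0.86, 2.17 and 1.30 against -0.08 and 0.27. Without the 4 libraries that had the fewest transcripts, 11 lists were called, 6 of them among the 18. Ribosomal proteins (adjusted p = 0.4997), fatty acid oxidation (0.731) and glutathione (0.73) turned higher, and 9 lists lost the call, among them oxidative phosphorylation (0.296), the TCA cycle (0.0991), NF-kB (0.0991) and immediate early genes (0.783).

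By count, overlap of the genes called against WT lay mainly between Gls KO and DKO. The lists differed in length, so the counts do not rank the pairs by how much they share. Among 10506 well-expressed genes other than the targets, Mpc2 KO had 3 higher and 3 lower calls, Gls KO 43 and 38, and DKO 17 and 16. Mpc2 KO shared 1 higher and 1 lower call with each of the others and 1 call of opposite direction with Gls KO. Independent lists would share 0.0123 and 0.0109 with Gls KO and 0.00485 and 0.00457 with DKO. Gls KO and DKO shared 12 higher and 7 lower calls, where independent lists of those lengths would share 0.0696 and 0.0579. Both comparisons use the same WT libraries, and with these split between them the latter became 6 to 7 higher and 2 to 5 lower, and the lower call shared with Mpc2 KO was lost. The 12 shared higher calls include Gm6472, Morf4l1-ps1, Hmga1b and Gm10184, and the 7 lower ones Kpna2 and Eif3j1, each with a near-identical copy. Fold changes of the 10506 genes correlated across genes with r = 0.765 for Gls KO and DKO, 0.693 for Mpc2 KO and DKO and 0.512 for Mpc2 KO and Gls KO; genes are not independent replicates. Unchanged groups simulated together with 1 shared WT group gave mean r of 0.508, 0.499 and 0.501. With the WT libraries split between the comparisons, mean r was 0.720, 0.625 and 0.456. The covariances were 0.204, 0.145 and 0.105 against simulated values of 0.0255, 0.0252 and 0.0252. Each gene was simulated on its own, so the simulations lack the variation that genes share within libraries. The excess over them therefore does not show a shared response to genotype.

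Adding Mpc2 deletion to Gls deletion was tested as DKO against Gls KO, where 34 genes were called, 18 higher and 16 lower, with 1803 at an unadjusted p under 0.05. Mpc2 was not called (-1.04, SE 0.35, adjusted p = 0.292). Kcnip3 (3.34, SE 0.24, adjusted p = 2.46e-08), Bcat1 (2.29, SE 0.16, adjusted p = 2.46e-08), Caskin2 (2.19, SE 0.29, adjusted p = 0.000205) and Tie1 (1.33, SE 0.17, adjusted p = 0.000205) were higher in DKO. Hebp1 (-2.99, SE 0.33, adjusted p = 2.4e-05), Trim12c (-1.07, SE 0.10, adjusted p = 2.01e-06), Fam102b (-0.98, SE 0.09, adjusted p = 3.27e-06) and Dhcr24 (-0.73, SE 0.13, adjusted p = 0.0137) were lower. Of 21 lists called, cholesterol synthesis was lower, 22 of 24 fitted lower with a median of -0.35 (adjusted p = 6.93e-08, adjusted p = 0.173 with an estimated correlation and adjusted p = 0.00287 with fry), and 6 members passed when adjusted over the list alone, among them Sqle (-0.65, SE 0.16), Ldlr (-0.87, SE 0.22) and Stard4 (-0.39, SE 0.11). G2 and M genes (adjusted p = 5.17e-05), monocyte and dendritic genes (9.61e-06) and late neutrophil genes (0.000135), which were higher in Gls KO than in WT, were lower in DKO than in Gls KO, each with an adjusted p of 0.563 with an estimated correlation. Both comparisons use the same Gls KO libraries, so spread among these alone gives opposite signs. With the S100a8 covariate G2 and M (0.022) and monocyte genes (0.000332) stayed lower, and without the 4 libraries that had the fewest transcripts late neutrophil genes were no longer called (0.811).

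Markers of stem and multipotent progenitors were higher in DKO than in Gls KO (adjusted p = 0.00839, and adjusted p = 0.563 with an estimated correlation), with Tie1 as the only member past the threshold. The 16 other lists called in this comparison were 15 lower lists of metabolism, ribosomes, stress and the G1 and S phases, and immediate early genes, which were higher (adjusted p = 1.72e-05); their adjusted p with an estimated correlation lay between 0.563 and 0.772. Without the 4 libraries that had the fewest transcripts, 5 of these 16 turned: ribosomal proteins (adjusted p = 4.66e-05) and fatty acid oxidation (0.0493) were then called higher, and oxidative phosphorylation (0.202), glutathione (0.677) and immediate early genes (0.431) were not called. Stem and multipotent markers lost the call (0.183). Asns, asparagine synthetase, was the member of the glutamine list with the smallest p (-0.99, SE 0.21, adjusted p = 0.0573), and it passed when adjusted over the list alone. Leaving out single libraries moved the count of 34 to 95 and 89 without DKO replicates 2 and 3, to 76 without Mpc2 KO replicate 4, and to 20 to 22 without Gls KO replicates 1, 3 or 4 or DKO replicate 5. Dhcr24 was lost without Gls KO replicate 3 or 5, without DKO replicate 1 or 5, with only the 2 groups fitted and without the 4 libraries that had the fewest transcripts (highest adjusted p 0.255), while its fold stayed at -0.84 to -0.63 over all settings.

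Adding Gls deletion to Mpc2 deletion, tested as DKO against Mpc2 KO, called 52 genes, 34 higher and 18 lower, with 1183 at an unadjusted p under 0.05. Gls fell (-3.66, SE 0.55, adjusted p = 0.00144), and Fhl2 (5.18, SE 0.42, adjusted p = 3.96e-07), Cd14 (1.79, SE 0.22, adjusted p = 0.000107) and Fam129c (1.5, SE 0.22, adjusted p = 0.000714) rose as they did when Gls was deleted alone. Slc25a42, a mitochondrial carrier of coenzyme A, rose (1.04, SE 0.19, adjusted p = 0.00974), and Bcat1 (-1.46, SE 0.15, adjusted p = 1.05e-05) and Esr1, the estrogen receptor (-0.56, SE 0.10, adjusted p = 0.00678), fell. Slc25a42 and Fam129c were lost with only the 2 groups fitted and without the 4 libraries that had the fewest transcripts (highest adjusted p 0.727 and 0.105), and Esr1 with only the 2 groups fitted (0.28). Of 15 lists called, 1, the immediate early genes, was higher (adjusted p = 0.00782) and 14 were lower. Oxidative phosphorylation genes had the smallest adjusted p, 42 of 42 fitted lower (adjusted p = 2.3e-06). With an estimated correlation the adjusted p of the 15 lay between 0.823 and 0.848, and 12 of the 15 lost the call with some single library left out. Ribosomal proteins were called higher with the length-slope covariate (adjusted p = 0.0348), and immediate early genes turned lower without the 4 libraries that had the fewest transcripts (0.703). In the ribosome biogenesis list (adjusted p = 0.00181) Odc1, which encodes ornithine decarboxylase, was called (-0.49, SE 0.10, adjusted p = 0.0287). Leaving out Mpc2 KO replicate 4 gave 83 calls.

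The interaction asks whether the effect of 1 deletion differs when the other is present, and 14 genes were called, 7 higher and 7 lower, with 646 at an unadjusted p under 0.05. That is again a share below 0.05 of the 14434 genes tested. Tie1 stood higher in DKO than the single effects add up to (1.48, SE 0.24, adjusted p = 0.00643), and Hebp1 (-2.81, SE 0.44, adjusted p = 0.00483), Trim12c (-1.20, SE 0.14, adjusted p = 0.000112), Alg8 (-1.10, SE 0.18, adjusted p = 0.00524) and Fam102b (-0.94, SE 0.13, adjusted p = 0.00152) lower. Kcnip3 (3.63, SE 0.31, adjusted p = 1.04e-06) and Bcat1 (1.32, SE 0.22, adjusted p = 0.00643) were higher than additive, at 25.7 ± 2.71 and 11.1 ± 1.64 CPM in DKO. Tie1 was lost with the Y-linked covariate and without the 2 WT libraries that lack Xist (highest adjusted p 0.061), Bcat1 with the length offset and with voom (0.389), and Alg8 with the length offset (0.301). Of 7 lists called, G2 and M genes were lower, 22 of 22 (adjusted p = 1.53e-07), as were monocyte and dendritic genes (0.00017), cholesterol synthesis (0.00017), late neutrophil genes (0.00689), the G1 and S phases (0.00872) and oxidative phosphorylation (0.0172), while stem and multipotent markers were higher (0.00486). With an estimated correlation the adjusted p of these 7 lay between 0.839 and 0.877, and leaving out 1 library gave 3 to 19 lists. Oxidative phosphorylation turned without the 4 libraries that had the fewest transcripts (0.999) and with the S100a8 covariate (0.204), and in the former late neutrophil genes (0.84), the G1 and S phases (0.0879) and stem and multipotent markers (0.0599) lost the call.

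Lists for other blood and marrow cells were tested for cells outside the sorted population. Some of these marker lists were called with the preset correlation, as given above. Late neutrophil and monocyte and dendritic lists were higher in Gls KO than in WT (adjusted p = 7.21e-08 and 2.51e-07). Stem and multipotent markers were higher in DKO than in Gls KO (0.00839). The marker lists therefore do not exclude such cells. Erythroid and megakaryocyte, B lymphoid, T and NK lymphoid, basophil, mast cell and eosinophil, and macrophage and stroma lists were not called in any of the 6 comparisons, with lowest adjusted p of 0.296, 0.256, 0.314, 0.347 and 0.196. Amino acid transport (0.378), hypoxia (0.0958), p53 targets (0.514) and sex-linked genes (0.367) were not called either. Of the 5 sex-linked genes, 4 passed lower when adjusted over the list alone in Mpc2 KO and in Gls KO against WT, and 1 was fitted higher. The list medians there were -3.36 and -2.79, so the missing call does not mean that these genes were unchanged.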

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

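Of the tests in this part, those of the axis of variation within groups, of summed copies, of neighbouring genes, of genes near Gls, of a wrong label and of intact Gls in DKO replicates 2 and 3 were chosen after the result was seen.

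The first pattern is that many genes moved together in DKO against WT, with 1753 at an unadjusted p under 0.05 of which 52 were called. A difference in RNA quality may contribute: over 8200 expressed genes, the fold followed the main axis of variation within the WT and Gls KO groups (Spearman rho across genes 0.672). That axis held 36.1% of the variance within these 2 groups, and the fold also followed transcript length (rho 0.481). The 3 DKO libraries with the steepest length slopes, replicates 1, 4 and 5, are also those with the least Mpc2 in the group. This design therefore does not part RNA quality from a deeper loss of Mpc2 on top of Gls, which stays open and untested.

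The second pattern concerns the 106 genes called between Gls KO and WT, of which 36 have a near-identical copy. These 36 fall in 32 families, and with counts of the copies summed 5 of the 32 stayed called. That loss does not decide whether reads moved between copies: in 21 of the 27 families that lost the call, the called genes held the smaller part of the summed counts in both groups, so adding the other members can hide a change. Some sums did not rise with the called gene. Hmga1b went from 0.273 CPM in WT to 188 in Gls KO and its family from 590 to 577. Gm6472 went from 0.0308 to 335 and its family from 1292 to 1175. Other sums rose, as for Gm4316, from 71.4 to 142 with its family from 690 to 886. Reads moved between copies stay open, and a pair such as Eif3j1 and Eif3j2, which moved in opposite directions with a sum of 159 CPM in WT and 149 in Gls KO, shows what they could give. Of the 106, 44 had another called gene within 2 Mb, against a mean of 26.8 and a highest value of 50 in 10000 random sets of tested genes (permutation p = 0.0029), which stayed below the bound of 2 times written for linked strain variants and leaves that explanation open. Within 20 Mb of Gls lay 6 of the other 105 called genes where 1.40 were expected (odds ratio 4.61, Fisher p = 0.00277), which is consistent with variants carried along with the floxed Gls allele. They are Fhl2, Slc40a1, Acadl, Als2, Il1r1 and Il1rl2, and an effect of glutaminase loss on them stays possible and untested.

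The third pattern is that Mpc2 stood at 79.8% and 64.6% of the WT mean in DKO replicates 2 and 3. Cells or reads with both genes intact would raise Gls alike, and Gls was at 11.7% and 2.47% there. A wrong label, with these libraries taken from the Gls KO group, is argued against by single genes chosen after their values were seen. In these 2 libraries Kcnip3 was at 26.8 and 29.6 CPM against 0.82 to 3.92 in Gls KO, Bcat1 at 13.5 and 11.6 against 1.79 to 2.91, Tie1 at 77.3 and 85.7 against 20.9 to 33.3, Trim12c at 22.3 and 19 against 33.5 to 43.8, and Hebp1 at 4.54 and 4.40 against 18.6 to 32.4. Trim12c may share reads with a near-identical copy. A test over all genes called between DKO and Gls KO without the library in question did not reach the bound set for excluding it, 50%: replicate 2 lay outside all Gls KO libraries on the DKO side in 38 of 81 genes (46.9%) and replicate 3 in 34 of 74 (45.9%). A sixth Gls KO library would do so in about 1 of 6 genes chosen without regard to these libraries. These genes were called with the same Gls KO libraries, so that share can be higher here and is no firm baseline. A score placing them between Gls KO and the other 3 DKO libraries was computed with 4 sets of genes and then removed, since it grouped the DKO libraries by their measured Mpc2; it had not decided the question. Incomplete deletion of Mpc2 was not tested.

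Other ways to split the libraries were counted for each comparison, 60 splits with the real one included. As many genes as in the real split were called by 1 split of 60 in Mpc2 KO against WT (8 genes, highest other 1), by 1 in Gls KO against WT (106, highest other 0), by 1 in DKO against WT (52, highest other 0) and by 2 in the interaction (14, highest other 528). These shares lie under 0.05, without correction for the number of counts compared. Splits that mix changed with unchanged libraries also widen the spread within groups, which can lower their own counts. For the interaction the libraries were reassigned over all 4 groups, so its splits test for any group difference and not for an interaction. Chance cannot be excluded for DKO against Mpc2 KO, where 7 splits called 52 or more (highest other 6748), or for DKO against Gls KO, where 3 called 34 or more (highest other 1165). The 3 splits with most genes, 6748, 4346 and 3420, put DKO replicates 1, 4 and 5 and Mpc2 KO replicate 4 on 1 side, and the split with 1165 put DKO replicates 1, 4 and 5 with Gls KO replicates 2 and 3, so these counts reflect a structure of the libraries that the genotype labels do not follow. For lists called, chance cannot be excluded in Mpc2 KO against WT (29 splits with 12 or more, highest other 17), Gls KO against WT (54 with 5 or more, highest other 13), DKO against WT (3 with 18 or more, highest other 21), DKO against Mpc2 KO (17 with 15 or more, highest other 20) and the interaction (39 with 7 or more, highest other 20). In DKO against Gls KO only the real split reached 21, with 19 as the highest other, again without correction.

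Named genes and library measures gave 164 sets of 5 libraries, each set 1 gene or measure in 1 group. In 14 sets 1 value lay apart from the other 4 by Dixon's ratio (above 0.71). Chance gives that in about 1 set of 20, so several of the 14 can be chance. In WT these were Hmga1b at 0.963 CPM in replicate 5 and Fhl2 at 1.72 in replicate 1. In Mpc2 KO they were St6galnac2 at 7.03, Depdc7 at 1.11 and Jmjd7 at 12.1 CPM in replicate 4, Prag1 at 2.33 in replicate 5, Fam129c at 6.37 in replicate 2, S100a8 at 314 in replicate 5 and the percentage of counts from the mitochondrial genome, 4.07 in replicate 5 against 2.32 to 2.68 in the others. In Gls KO it was Caskin2 at 6.29 CPM in replicate 4. In DKO they were Nrg1 at 18.6, Slc40a1 at 57.8 and S100a8 at 734 CPM in replicate 3 and Jmjd7 at 1.93 in replicate 1. Mpc2 KO replicate 4 also had the largest share of reads on unmatched transcripts, 1.27% against 0.614% to 0.702% in WT.

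The interaction was called for 14 genes, with values on the log2 scale of 3.63 for Kcnip3, 2.23 for Kpna2, 2.04 for Caskin2, 1.48 for Tie1, 1.32 for Bcat1, 1.16 for Eif3j1, -0.94 for Fam102b, -1.10 for Alg8, -1.20 for Trim12c and -2.81 for Hebp1. Predicted genes made up the rest: Gm16867 at 7.36, Gm15987 at -3.58, Gm3608 at -5.44 and Gm6472 at -12.50. Neighbouring genes were examined for Gls KO against WT only. Linked strain variants that differ between the groups were therefore not tested for these genes or for those called in DKO. Caskin2 kept its call in 9 of 32 other settings and in 3 of 20 fits with 1 library left out (highest adjusted p 0.482), and Eif3j1 lost it with the transcript length offset (0.997). The value for Gm6472 depends on the prior count, since its WT mean was 0.0308 CPM, and Gm6472 is a near-identical copy of Rps7. Trim12c had a value in 31 other settings, as did Kpna2 and Eif3j1, and may likewise share reads with a copy.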

How the results depend on the processing

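Of the settings in this part, the 4 libraries with the fewest transcripts left out, the 2 WT libraries without Xist left out, summed copies, the S100a8 covariate and the length-slope covariate were chosen after the data were seen. Over all named genes, 2534 recomputed values gave the same call, 436 lost it and 0 changed direction. Over all called lists, 1851 gave the same call, 384 lost it and 27 changed direction.

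Genes called between Mpc2 KO and WT, 8, became 19 with DESeq2, 27 with voom and sample weights, 4 with the transcript length offset and 1 with only the 2 groups fitted. They became 13 without the 4 libraries with the fewest transcripts and 3 without the 2 WT libraries that lack Xist. Leaving out 1 library gave 2 to 10: 2 without Mpc2 KO replicate 2, 4 without WT replicate 1, and 5 without Mpc2 KO replicate 5, WT replicate 2 or WT replicate 5.

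Between Gls KO and WT, 106 became 231 with DESeq2, 1096 with voom and sample weights, 69 with the length offset, 458 with only the 2 groups fitted and 304 with the length-slope covariate. The count was 311 without the 4 libraries with the fewest transcripts, 51 without the WT libraries that lack Xist and 61 with copies summed. With 1 library left out it was 65 to 180: 180 without Mpc2 KO replicate 4, and 69, 67 and 65 without WT replicates 2, 3 and 4.

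Between DKO and WT, 52 became 171 with DESeq2, 138 with voom, 89 with the length-slope covariate and 90 with the S100a8 covariate. It was 79 without the 4 libraries with the fewest transcripts, 33 without the WT libraries that lack Xist and 27 with copies summed. The range with 1 library left out was 39 to 209, with 209 without DKO replicate 2 and 96 without Mpc2 KO replicate 4.

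Between DKO and Mpc2 KO, 52 became 131 with DESeq2, 90 with voom, 15 with only the 2 groups fitted, 116 with the length-slope covariate, 83 with the S100a8 covariate and 31 with copies summed. When 1 library was left out, 41 to 83 were called, the latter without Mpc2 KO replicate 4. Between DKO and Gls KO, 34 became 158 with DESeq2, 92 with voom, 130 with the length-slope covariate and 19 with copies summed. Leaving out 1 library gave 20 to 95: 95 and 89 without DKO replicates 2 and 3, 76 without Mpc2 KO replicate 4, 22 without DKO replicate 5, and 21, 20 and 22 without Gls KO replicates 1, 3 and 4. The interaction's 14 became 31 with DESeq2, 23 with voom and 7 with copies summed, and leaving out 1 library gave 13 to 17.

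The targeted genes kept their direction in every setting. Gls against WT lost its call in DKO without the 4 libraries with the fewest transcripts (-3.80, adjusted p = 0.111), and so did Gls in DKO against Mpc2 KO (-3.76, adjusted p = 0.145), with 2 DKO libraries left. Mpc2 in Mpc2 KO lost its call with only the 2 groups fitted (-2.40, adjusted p = 0.141), without the WT libraries that lack Xist (-2.38, adjusted p = 0.0699) and without Mpc2 KO replicate 2 (-2.42, adjusted p = 0.0502). Mpc2 in DKO passed with voom and sample weights against WT (-1.31, adjusted p = 0.00264) and against Gls KO (-1.27, adjusted p = 0.00954), and with the length-slope covariate against Gls KO (-0.78, adjusted p = 0.0494). Its fold was smaller against WT with that covariate (-0.67) and without the 4 libraries with the fewest transcripts (-0.47), and against Gls KO with the S100a8 covariate (-0.70) and without the 4 libraries (-0.40). Leaving out 1 library gave -4.14 to -3.45 for Gls in Gls KO, -4.13 to -3.40 in DKO against WT and -4.15 to -3.42 against Mpc2 KO. For Mpc2 it gave -2.64 to -2.15 in Mpc2 KO, -1.37 to -0.90 in DKO against WT and -1.32 to -0.83 against Gls KO.

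Lists called fell to 0 with an estimated correlation in all 6 comparisons, and to 0 with fry except for 1 in DKO against WT and 1 in DKO against Gls KO. Other moves were 12 to 7 with voom in Mpc2 KO, 5 to 9 with the S100a8 covariate in Gls KO (7 of the 9 lower), and 18 to 11 without the 4 libraries with the fewest transcripts in DKO. DKO against Mpc2 KO moved from 15 to 8 with the length offset, 9 without the 4 libraries with the fewest transcripts and 6 with the length-slope covariate. DKO against Gls KO moved from 21 to 11 without the 4 libraries and to 12 with the S100a8 covariate. The interaction moved from 7 to 16 with voom. With single libraries left out, 11 of the 12 lists called in Mpc2 KO lost the call at least once, as did 1 of 5 in Gls KO, 3 of 18 in DKO against WT, 12 of 15 in DKO against Mpc2 KO, 10 of 21 in DKO against Gls KO and 4 of 7 in the interaction. Leaving out 1 library gave 9 to 13 in Mpc2 KO, 4 to 7 in Gls KO and 17 to 19 in DKO against WT. It gave 14 to 22 in DKO against Gls KO and 6 to 17 in DKO against Mpc2 KO (6 and 7 without DKO replicates 4 and 5, and 9, 7 and 7 without Mpc2 KO replicates 1, 2 and 5). In the interaction it gave 3 to 19 (14 without Gls KO replicate 3, 15 and 3 without DKO replicates 2 and 4, and 12, 19 and 4 without Mpc2 KO replicates 3, 4 and 5).

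Lists that changed direction in Mpc2 KO against WT were oxidative phosphorylation (adjusted p = 0.861 with voom, 0.106 without Mpc2 KO replicate 4, 0.0807 without the 4 libraries with the fewest transcripts), ribosomal proteins (0.957, 0.171 and 0.0807 in the same settings), NF-kB genes (0.861 with voom), immediate early genes (0.844 with voom), ER stress genes (0.884 without Mpc2 KO replicate 5) and primary granule genes (0.851 without Mpc2 KO replicate 4, 0.854 without the 4 libraries). Without Mpc2 KO replicate 5 the lower call was instead at 3.41e-11 for oxidative phosphorylation, 1.2e-10 for ribosomal proteins and 0.00117 for primary granule genes, and ER stress was at 8.57e-06 without replicate 4. Without the 4 libraries, fatty acid oxidation (0.731), glutathione (0.73) and ribosomal proteins (0.4997) turned in DKO against WT, and immediate early genes (0.703) in DKO against Mpc2 KO. In DKO against Gls KO the same setting turned oxidative phosphorylation (0.202), fatty acid oxidation (0.0493), glutathione (0.677), ribosomal proteins (4.66e-05) and immediate early genes (0.431), and in the interaction oxidative phosphorylation (0.999). Ribosomal proteins also turned with the length-slope covariate in DKO against Mpc2 KO (0.0348) and DKO against Gls KO (0.454). The S100a8 covariate turned ribosomal proteins (0.267) and fatty acid oxidation (0.882) in DKO against Gls KO, and oxidative phosphorylation (0.204) in the interaction, and late neutrophil genes (0.759), which include S100a8 itself, so that value tests nothing.

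The correlation of Mpc2 KO with Gls KO fold changes, 0.512, ranged from 0.244 to 0.546 with 1 library left out (0.244 without Gls KO replicate 2, 0.428 without Mpc2 KO replicate 5). That of Mpc2 KO with DKO, 0.693, became 0.625 with split WT libraries and ranged from 0.545 (without Mpc2 KO replicate 4) to 0.716. That of Gls KO with DKO, 0.765, ranged from 0.561 (without Gls KO replicate 2) to 0.822 (without DKO replicate 4), with 0.705 and 0.653 without DKO replicates 2 and 3. The authors' table held 18 genes, and 6 with a fold threshold of 1 on the log2 scale.

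The replicate numbers were not used as pairs. Of 30 pairs of groups sharing a number, 8 had a correlation over 0.1 (range -0.56 to 0.75), and 7 of 20 libraries matched their own number best. A setting that left out the 6 libraries with S100a8 above 100 CPM was run, seen and removed, since it chose libraries by a measured outcome and left 1 Gls KO library; in it 3 lists of Gls KO against WT changed direction. The S100a8 covariate replaced it. 2 more settings, which left out DKO replicates 2 and 3 for the Mpc2 they kept, with and without the length-slope covariate, were also run, seen and removed for choosing libraries by a measured level. Without the covariate the first had called many times more genes in DKO against WT and against Gls KO than all 5 libraries do, and those 3 DKO libraries also have the steepest length slopes.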

Other observations

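The relation of residual Gls to Y-linked RNA was chosen for testing after the values were seen, as were the remarks on single genes in this part.

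Bcat1 was called in each comparison except DKO against WT (-0.49, SE 0.15, adjusted p = 0.255). It was at 15.6 ± 2.35 CPM in WT, 30.6 ± 4.87 in Mpc2 KO, 2.26 ± 0.408 in Gls KO and 11.1 ± 1.64 in DKO (SD, n = 5 each), and the ranges of the 4 groups overlapped only between WT and DKO. Its product moves amino groups between branched-chain amino acids and glutamate, the product of glutaminase. The fold stayed past the threshold in all 33 other settings for Gls KO against WT, for DKO against Mpc2 KO and for DKO against Gls KO, and in 31 of 33 for Mpc2 KO against WT, where it was lost with only the 2 groups fitted and without the WT libraries that lack Xist. Its interaction kept the call in 30 of 32, losing it with the length offset and with voom. No near-identical copy of Bcat1 was found that would take its reads. Glutamate was not measured here, and a strain variant near Bcat1 was not tested.

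Asns was at a log2 change of -0.99 in DKO against Gls KO (SE 0.21, adjusted p = 0.0573), just outside the threshold over all genes. Of the 25 genes of the integrated stress list, 16 were fitted lower and 9 higher. Adjusted over that list alone, Asns and Aars (-0.45, SE 0.11) passed lower and Ppp1r15a (0.84, SE 0.26) higher.

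Cholesterol synthesis genes were lower in DKO than in WT with the 4 libraries that had the fewest transcripts left out (adjusted p = 2.76e-05) and lower than in Gls KO (adjusted p = 2.28e-08), while oxidative phosphorylation genes lost the call in the first (adjusted p = 0.296) and turned higher in the second (adjusted p = 0.202). With an estimated correlation the cholesterol list was not called in either comparison with all libraries (adjusted p = 0.432 and 0.173). That DKO group then holds replicates 2 and 3 alone, the 2 that kept most Mpc2.

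Residual Gls in the 10 libraries of Gls KO and DKO followed Y-linked RNA. Over the 10 libraries the correlation of the Gls level with the mean of 4 Y-linked genes was r = 0.819 (permutation p = 1e-05, the smallest that 100000 resamples can give), with a Spearman rho of 0.976 (p = 3e-05). Without the 2 farthest libraries, DKO replicate 4 and Gls KO replicate 3, r was 0.935 (n = 8, permutation p = 0.00057). A candidate explanation is RNA from male cells with Gls intact. The slope was 0.583% of the WT Gls mean for each 1% of the Y-linked level of the WT libraries that lack Xist, and rests on DKO replicate 4: without it the slope was 1.58, and without any other single library 0.542 to 0.588. Xist was at 750 CPM or more in all 10 libraries, so most RNA came from cells with an inactive X chromosome. Such cells alone would give a slope of 1, which these values neither match nor exclude, and the labels do not describe a source for them. Sequence differences between the residual Gls reads and the floxed allele would test it.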
